A study of Aspergillus nidulans with 6 samples.

How the data were processed

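Per the labels' protocols, total RNA from lyophilized mycelium was made into libraries with the TruSeq RNA kit, and no step that selects or depletes RNA is named. The cultures were the Aspergillus nidulans wild type FGSC A4, grown in minimal broth and either left untreated or given 35 mM tyrosol in exponential phase. The 6 libraries form 2 groups of 3, taken from the treatment given for each sample. Nothing in the labels says that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

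The submitters' processing notes name FastQC, HISAT2 2.1.0, DESeq2 1.24.0 and edgeR, with no role for each. The genome build, annotation, read counter and strand setting are not given in the sources used here. Reads of overlapping genes, of antisense partners and of near-identical copies may therefore be shared between features, and values of such genes are uncertain. The deposited table holds, per the file headers, a read count, a gene length and an RPKM value for each of 10988 features in each library. Of these, 10748 are genes with an AN number, 208 are tRNAs and 31 are upstream open reading frames. The deposited counts are whole numbers and were not normalized. The deposited RPKM values equal the count divided by the listed length and the column total, scaled as RPKM, with a largest relative difference of 1.26e-14. Columns headed T were read as the tyrosol libraries and columns headed K as the untreated ones, K being taken as the Hungarian word for control. The column numbers were taken as the replicate numbers in the sample titles.

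The libraries held 9353438 to 11917409 counted reads, which limits the precision of weakly expressed genes. No pair of replicates agreed within sampling noise: chi-square per degree of freedom lay between 5.15 and 23.0 over features with at least 20 reads in a pair. Gene symbols came from a RefSeq gene table of assembly ASM1142v1, which paired 10029 features (91.3%) with a gene and gave a symbol to 778. The table carries no product descriptions, so the 26 lists planned on product descriptions could not be built. Many of its symbols follow the names of related genes in other fungi. The build behind the counts is not known, so that table served only for names and for which genes neighbour each other.

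The counts were tested with edgeR 4.0.16 in R 4.3.3. Features were filtered with filterByExpr, scaled with TMM factors and tested with the two-sided quasi-likelihood test, tyrosol against untreated, with no covariate. A feature was called changed at a Benjamini-Hochberg adjusted p under 0.05, and a log2 fold change of at least 1 in size gave the calls of at least 2-fold. On data simulated for this comparison, with 8827 genes passing the filter, the test recovered 69.7% of 66 genes changed 1.5-fold, 95.4% of 65 changed 2-fold and 100% of 65 changed 4-fold. In the same simulation 6.99% of the calls were false. The simulation left 8631 genes unchanged, whereas most tested features were called changed in the real comparison, so these rates may not hold there.

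Gene lists were tested with limma 3.58.1: camera on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01, two-sided, adjusted over the lists tested. The same test with an estimated correlation and fry were alternatives. Fisher's exact test, two-sided, compared each list with the other features among raised and among lowered genes. The 26 lists of gene symbols, the tests and the alternatives were fixed before the data were examined. Of these lists, 8 had at least 3 tested members named by the reference table. A further 20 lists were assembled from the reference table's symbols after the data had been seen, and their tests are descriptive for that reason. Both list tests were repeated against the 760 named tested features alone, a choice made after the data were seen, because only named features can enter a list.

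The genes named are the 10 largest rises and 10 largest falls among named genes with an adjusted p under 0.05, non-overlapping groups and a mean log2 CPM of at least 3. To these come up to 4 members with the smallest adjusted p in each list described, and a set of genes fixed before the data were examined wherever the table gives their symbol. At most 2 unnamed IDs per direction were added, and genes named outside this rule are said to have been chosen after their values were seen.

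The alternatives were DESeq2 1.42.0 size factors, upper-quartile factors and library size alone, no filter on low counts, a filter of 50 reads in 3 libraries, the DESeq2 Wald test, limma-voom, limma on log2(RPKM + 1), the replicate number as a block, a threshold of 0.01, a test against a 2-fold change, and leaving out each library in turn. Removal of the 50 features with most reads, thinning to the smallest library and removal of a length trend were added after the data were seen. Gene IDs that were assigned to list symbols from memory before the data were examined entered one alternative only. Figures were drawn with matplotlib 3.10.9.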

Results

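RNA was sequenced from mycelium of Aspergillus nidulans, a filamentous fungus, in 3 untreated and 3 tyrosol libraries. The tyrosol cultures had been given 35 mM tyrosol in exponential phase. Tyrosol is a phenolic alcohol derived from tyrosine that some fungi release as a signal between cells. Untreated replicates 1, 2 and 3 held 11917409, 11904236 and 9353438 counted reads, and tyrosol replicates 1, 2 and 3 held 10632981, 11242154 and 11506581. The comparison asks which transcripts change in abundance on exposure to tyrosol. Values are mean RPKM ± SD over 3 libraries, log2 fold changes are tyrosol over untreated ± SE, and adjusted p-values are from edgeR's quasi-likelihood test. The SE is the size of the log2 fold change divided by the square root of that test's F statistic. RPKM values are scaled by library totals and log2 fold changes by TMM factors, so ratios of the RPKM means differ somewhat from the fold changes.

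The genes of homogentisate breakdown, the route that opens the aromatic ring of tyrosine, had the largest rises among named genes. The fumarylacetoacetase gene fahA went from 2.03 ± 0.287 to 941 ± 85.4 RPKM, a log2 fold change of 9.06 ± 0.14 (adjusted p = 4.3e-14). The homogentisate dioxygenase gene hmgA went from 2.90 ± 0.373 to 625 ± 56.2 RPKM, a log2 fold change of 7.96 ± 0.13 (adjusted p = 4.3e-14). The neighbouring hmgX also had a log2 fold change of 7.96 ± 0.15, and the maleylacetoacetate isomerase gene maiA one of 7.28 ± 0.15. In the opposite direction the nitrite reductase gene niiA went from 1071 ± 129 to 173 ± 4.79 RPKM and the catalase gene catA from 7.76 ± 2.76 to 0.159 ± 0.0374 RPKM.

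The change was broad. Of 8905 features tested, 7432 (83.5%) changed, 3616 of them raised and 3816 lowered. A change of at least 2-fold was found for 4235 features (47.6%), with 2057 raised and 2178 lowered. The 3 libraries of one group lay entirely beyond the 3 of the other for 84.8% of tested features, against 10% by chance. Correlations of log2 CPM across features were 0.989 to 0.995 within a group and 0.755 to 0.771 between groups, and the first principal component, which separated the groups, held 96.1% of the variance. Among 760 named features tested, 265 rose, 384 fell and 111 did not pass. Among unnamed features 3351 rose and 3432 fell. With library size as the only scaling, the median log2 fold change of all features shifted by -0.22 relative to TMM scaling, and 3069 rose and 4401 fell. Rises and falls are therefore relative to the other features, and the balance between them depends on the scaling.

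Beyond the homogentisate genes, the largest rises among named genes were in pst2, mfs56, faeB-2, aah1, met2 and aguA. The pst2 transcript became one of the abundant ones, going from 61.9 ± 4.04 to 4533 ± 126 RPKM with a log2 fold change of 6.42 ± 0.10 (adjusted p = 4.3e-14). The log2 fold changes were 6.31 ± 0.21 for mfs56, 4.89 ± 0.15 for faeB-2, 4.71 ± 0.15 for aah1, 3.95 ± 0.09 for met2 and 3.94 ± 0.18 for aguA. The largest falls were in catA (-5.35 ± 0.39), the arginine methyltransferase gene rmtA (-4.96 ± 0.13), the conidiation regulator gene flbC (-4.75 ± 0.13), the hydroxymethylglutaryl-CoA synthase gene erg13 (-4.73 ± 0.13) and the ATP sulfurylase gene sC (-4.58 ± 0.13). They were followed by spb4, mak5, dbp4, loc1 and nop7, all genes of ribosome assembly, at -4.54 to -4.29. The catA gene had 274, 268 and 104 reads in the untreated libraries and 3, 5 and 5 in the tyrosol libraries. With so few tyrosol reads the size of its fall is imprecise. Among unnamed genes, AN6420 had 10, 7 and 3 reads in the untreated libraries and 5649, 5870 and 6159 in the tyrosol libraries. AN2471 had 1, 1 and 0 reads untreated and 966, 931 and 1008 with tyrosol. Among unnamed genes with a mean log2 CPM of at least 3, the largest falls were in AN5564 (-5.90 ± 0.12) and AN7989 (-5.85 ± 0.25).

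**Figure D1:**
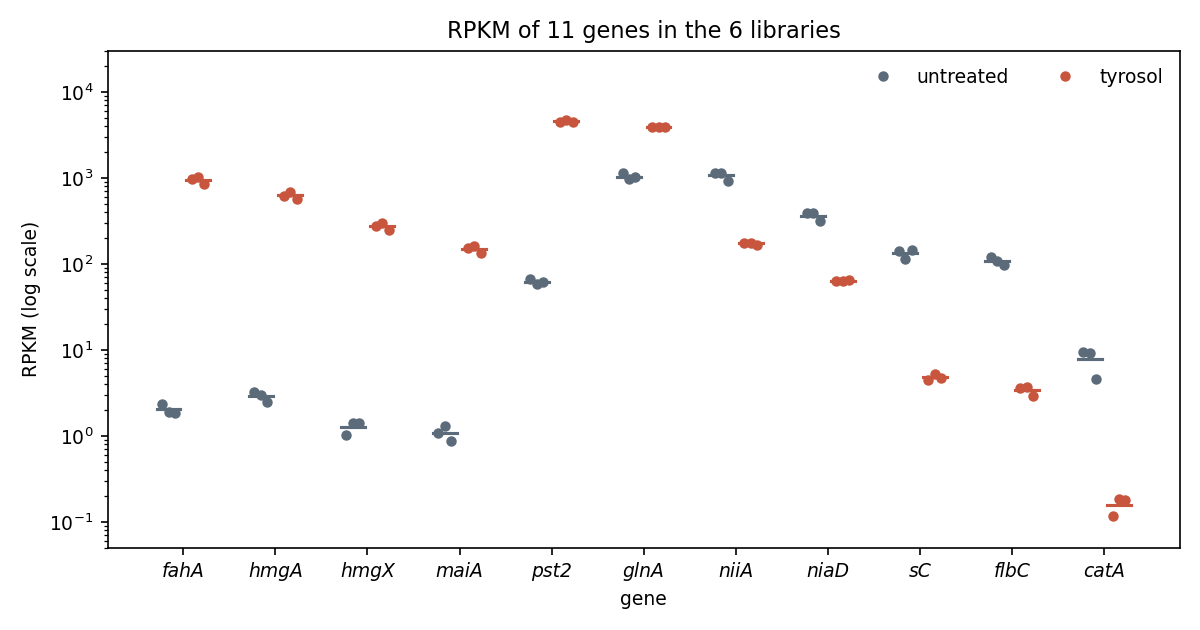
RPKM on a log axis of 11 genes, with a point for each of the 3 untreated and 3 tyrosol libraries and a bar at each group's mean. The groups do not overlap for any of these genes: fahA averaged 2.03 RPKM untreated and 941 with tyrosol, and catA 7.76 and 0.159.

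Of the lists fixed before the data were examined, 8 could be tested, and 2 moved relative to other genes by camera with the preset correlation. The counts adjusted over the list alone were the same as those over all genes tested in each of these 8 lists. All 3 tested genes of tyrosine, homogentisate and phenylacetate breakdown (hmgA, fahA, maiA) rose, and so did all 3 adjusted over the list alone, with a median log2 fold change of 7.96 (camera adjusted p = 0.0283, and adjusted p = 0.494 with an estimated correlation). Of 14 conidiation genes 11 fell, 2 rose and 1 did not pass, with a median of -1.48 (camera adjusted p = 0.0283, adjusted p = 0.494 with an estimated correlation, and adjusted p = 0.0865 against named features alone). Within it flbC fell by 4.75, flbD by 3.24, the laccase gene yA by 2.58 and ivoB by 1.47 on the log2 scale. The central regulator brlA, at 25.7 ± 3.37 RPKM untreated, had a log2 fold change of -0.99 ± 0.11 (adjusted p = 1.8e-06).

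Nitrogen assimilation genes went both ways. Of 8 members 5 rose, 2 fell and 1 did not pass, with a median of 0.81 (camera adjusted p = 0.456). The nitrate reductase gene niaD had a log2 fold change of -2.29 ± 0.10 and niiA one of -2.41 ± 0.10, while the glutamine synthetase gene glnA went from 1036 ± 83.9 to 3904 ± 33.0 RPKM (2.14 ± 0.09) and the regulator areA rose by 1.63 ± 0.11. Iron acquisition genes were also divided, with 3 of 7 raised and 4 lowered and a median of -1.16 (camera, downward, adjusted p = 0.72; fry, upward, adjusted p = 0.575). The siderophore synthesis genes sidC and sidD fell by 2.31 and 2.97 on the log2 scale, and the transporter gene mirC and the repressor gene sreA rose by 1.86 and 0.87.

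Stress signalling genes included falls in sakA (-2.48 ± 0.09), atfA (-1.64 ± 0.15) and mpkC (-1.07 ± 0.11) and a rise in rlmA (0.74 ± 0.15). Of the 6 members 2 rose, 3 fell and 1 did not pass (camera adjusted p = 0.566). Among 5 regulators of secondary metabolism and light response 3 rose and 2 fell (camera adjusted p = 0.566). In that list veA rose by 1.76 ± 0.09 and the phytochrome gene fphA by 1.23 ± 0.10, while velB had a log2 fold change of -0.85 ± 0.11 and laeA one of -0.65 ± 0.11. Of 5 cell wall synthesis genes 4 fell, including chsB, chsG (-1.43) and csmB (-0.98), and chsD rose by 1.53 (camera adjusted p = 0.329). The chitin synthase symbols are those of the reference table, which may differ from other usage. All 4 tested members of the plant polysaccharide and starch breakdown list rose: cbhB by 1.75, the regulator gene xlnR by 1.68, xlnD by 1.31 and the repressor gene creA by 1.22. The camera adjusted p was 0.0619, with 0.582 for an estimated correlation and 0.0376 against named features alone. Because the list mixes breakdown enzymes with regulators, among them a repressor, its rise is not a rise of breakdown enzymes alone. That list passed camera also with library size only, no filter on low counts, limma-voom, limma on RPKM and without untreated replicate 1 (adjusted p = 0.0340 to 0.0445).

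In Fisher's exact test none of the 16 combinations of these lists with a direction was enriched among changed genes after adjustment, and 2 were at an unadjusted p under 0.05. With DESeq2, limma-voom or limma on RPKM in place of edgeR the count was also 0. Among genes changed at least 2-fold, 1 combination was enriched, the rise of plant polysaccharide and starch breakdown (4 of 4, Fisher adjusted p = 0.0455). Against named features alone Fisher's test gave 0 enriched combinations among changed genes, with 2 at an unadjusted p under 0.05. Among genes changed at least 2-fold it gave 2 there, the rises of plant polysaccharide and starch breakdown (adjusted p = 0.0105) and of tyrosine, homogentisate and phenylacetate breakdown (adjusted p = 0.0332).

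Lists assembled after the data had been seen describe more of the named genes, though many named genes are in no list. All 26 ribosome biogenesis genes fell, 25 of them at least 2-fold, with a median log2 fold change of -3.48 (camera adjusted p = 2.5e-09, and adjusted p = 0.361 with an estimated correlation). In that list has1 went from 81.3 ± 8.54 to 4.42 ± 0.265 RPKM and nop58 from 146 ± 8.02 to 9.13 ± 0.888 RPKM. All 6 translation initiation genes fell at least 2-fold, with a median of -1.83 (camera adjusted p = 0.00585, and adjusted p = 0.261 with an estimated correlation). There pab1 had a log2 fold change of -3.83 ± 0.10 and tif1 one of -1.99 ± 0.09. Of 8 tRNA modification genes 7 fell and 1 did not pass, with trm6 at -4.20 ± 0.18 (list median -1.77, camera adjusted p = 0.00585, and adjusted p = 0.52 with an estimated correlation). All 7 cytosolic ribosomal protein genes fell, with a smaller median of -0.59 (camera adjusted p = 0.0477, adjusted p = 0.535 with an estimated correlation, and adjusted p = 0.101 against named features alone). That list also failed to pass with DESeq2 size factors (camera adjusted p = 0.0517), with the filter of 50 reads in 3 libraries (0.0596) and with the replicate number as a block (0.0536). It failed too without the 50 features with most reads (0.0844) and when any library but untreated replicate 1 was left out (0.0546 to 0.0619).

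Sterol synthesis genes fell together. Of 17 members 16 fell and 1 rose, with a median of -1.45 (camera adjusted p = 0.000374, and adjusted p = 0.261 with an estimated correlation). The falls included erg13 (-4.73), erg4 (-3.77), erg24B (-2.67) and erg20 (-2.28). Of 11 chaperone genes 9 fell and 2 rose, with hsp70 at -2.89, hsp90 at -2.65, bipA at -2.37 and pdiA at -2.14 (camera adjusted p = 0.0221, adjusted p = 0.517 with an estimated correlation, and adjusted p = 0.0659 against named features alone).

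Genes of peroxisome assembly and autophagy rose. Of 12 peroxisome genes 11 rose and 1 did not pass, with a median of 1.29 (camera adjusted p = 0.0005, and adjusted p = 0.261 with an estimated correlation). The largest rise of these was in pex7, from 14.5 ± 0.965 to 126 ± 2.36 RPKM (3.35 ± 0.09). All 5 autophagy genes rose, among them atg15 by 2.37 ± 0.11 and atg1 by 2.22 ± 0.12 (list median 1.33, camera adjusted p = 0.0221, and adjusted p = 0.52 with an estimated correlation).

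The other 12 added lists did not pass camera with the preset correlation, TMM scaling and all tested features and libraries, though 3 of them passed camera under other scalings, filters, tools or libraries. Mitochondrial protein import passed with no filter on low counts, with limma-voom and without untreated replicate 1 (camera adjusted p = 0.0304 to 0.046), but not with an estimated correlation (0.52). Cell cycle and DNA replication passed with library size as the only scaling (0.0442) and with limma on RPKM (0.04996), but not with an estimated correlation (0.415). Secreted plant polysaccharide hydrolases passed with library size only, upper-quartile factors, limma on RPKM and without untreated replicate 1 (0.0339 to 0.0498). Of 12 secreted plant polysaccharide hydrolases 10 rose and 2 fell (median 1.15, camera adjusted p = 0.0584, adjusted p = 0.535 with an estimated correlation, and adjusted p = 0.0173 against named features alone). Of 21 amino acid biosynthesis genes 13 rose, 7 fell and 1 did not pass (median 0.92), with met2, lys1 (3.21) and argB (2.50) raised and sC lowered. Of 9 antioxidant enzymes and their regulators 7 rose and 2 fell (median 0.58), with skn7, cat1 (1.53) and yap1 (1.39) raised and catA lowered. Of 8 mitochondrial protein import genes 6 fell, 1 rose and 1 did not pass (median -0.84), with tom70 at -3.00 and tom40 at -2.16. Of 12 genes of the citric acid cycle and respiration 8 fell, 1 rose and 3 did not pass (median -0.26), with acoA at -2.24. Of 11 cell cycle and DNA replication genes 8 fell and 3 did not pass (median -0.48), with plkA at -2.54. Of 23 cell wall enzymes 16 fell, 4 rose and 3 did not pass (median -0.40). Of 4 zinc transporters 3 fell and 1 did not pass (median -1.81), with zrfA at -3.61 and zrfC at -3.19. Secretory pathway transport (8 genes) had 2 raised and 4 lowered, the spliceosome (13 genes) 4 raised and 6 lowered, and G protein signalling (13 genes) 4 raised and 7 lowered. The 15 proteasome genes had 6 raised, 3 lowered and 6 not passing with a median of 0.14, which turned to -0.09 with library size as the only scaling, where 2 were raised and 6 lowered.

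Fisher's exact test enriched 9 of 40 combinations of an added list with a direction among changed genes. The 9 were the falls of ribosome biogenesis, cytosolic ribosomal proteins, translation initiation, sterol synthesis, chaperones and cell wall enzymes (16 of 23, adjusted p = 0.037) and the rises of peroxisome assembly, autophagy and secreted plant polysaccharide hydrolases (10 of 12, adjusted p = 0.0227). Against named features alone 6 were enriched: ribosome biogenesis, sterol synthesis, peroxisome assembly, autophagy and secreted plant polysaccharide hydrolases kept their call, and the rise of antioxidant enzymes and their regulators was added (7 of 9, adjusted p = 0.0421). Cytosolic ribosomal proteins (adjusted p = 0.0554), translation initiation (0.0767), chaperones (0.138) and cell wall enzymes (0.161) lost theirs. The number of raised genes in the antioxidant list depended on the scaling: it was 7 with TMM, 6 with upper-quartile factors and 5 with library size only. Among genes changed at least 2-fold 5 of 40 were enriched against all tested features, the falls of ribosome biogenesis, translation initiation, sterol synthesis and tRNA modification (adjusted p = 0.0249) and the rise of peroxisome assembly. At that threshold secreted plant polysaccharide hydrolases (adjusted p = 0.0517), autophagy (0.0579), chaperones (0.103), cell wall enzymes (0.877) and cytosolic ribosomal proteins (1 of 7) did not pass. Against named features alone 8 were enriched at 2-fold: those 5 and the rises of autophagy (adjusted p = 0.0164), secreted plant polysaccharide hydrolases (0.00774) and amino acid biosynthesis (0.00628).

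**Figure D2:**
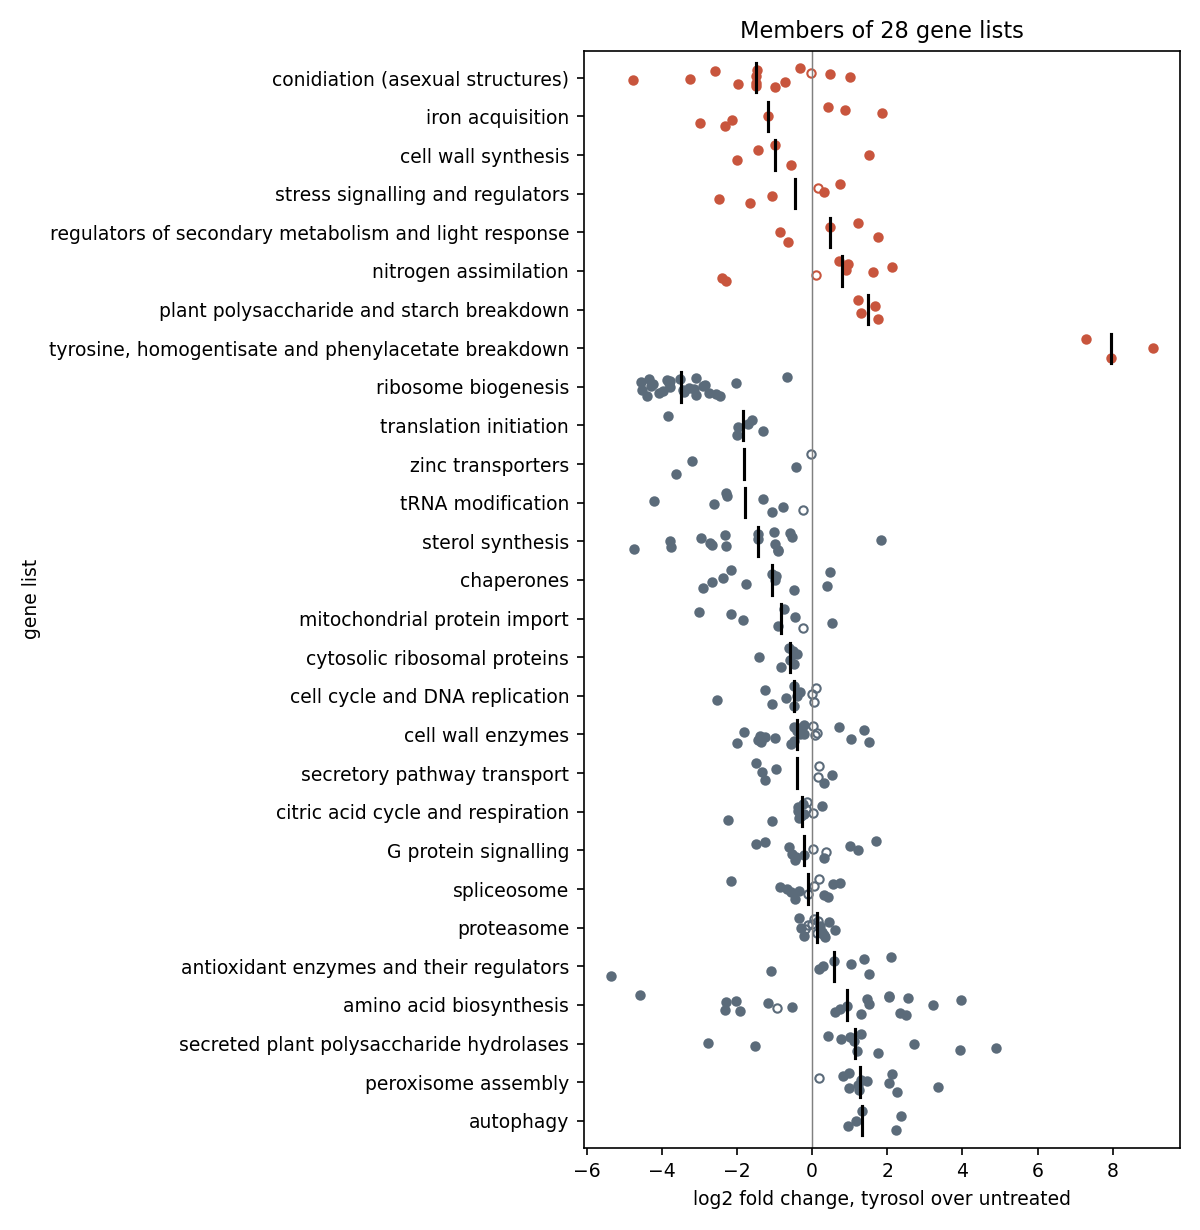
Log2 fold changes, tyrosol over untreated, of the members of 28 gene lists, with a point for each gene, open where the adjusted p was not under 0.05, and a black bar at the list's median. Red lists were fixed before the data were examined and grey lists were assembled afterwards; the median was 7.96 for tyrosine, homogentisate and phenylacetate breakdown and -3.48 for ribosome biogenesis.

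The homogentisate genes lie side by side in the reference table's gene order. The order runs maiA, fahA, hmgA and hmgX, and the next gene, AN1899, singled out after its value was seen, had a log2 fold change of 8.53 ± 0.13.

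**Figure D3:**
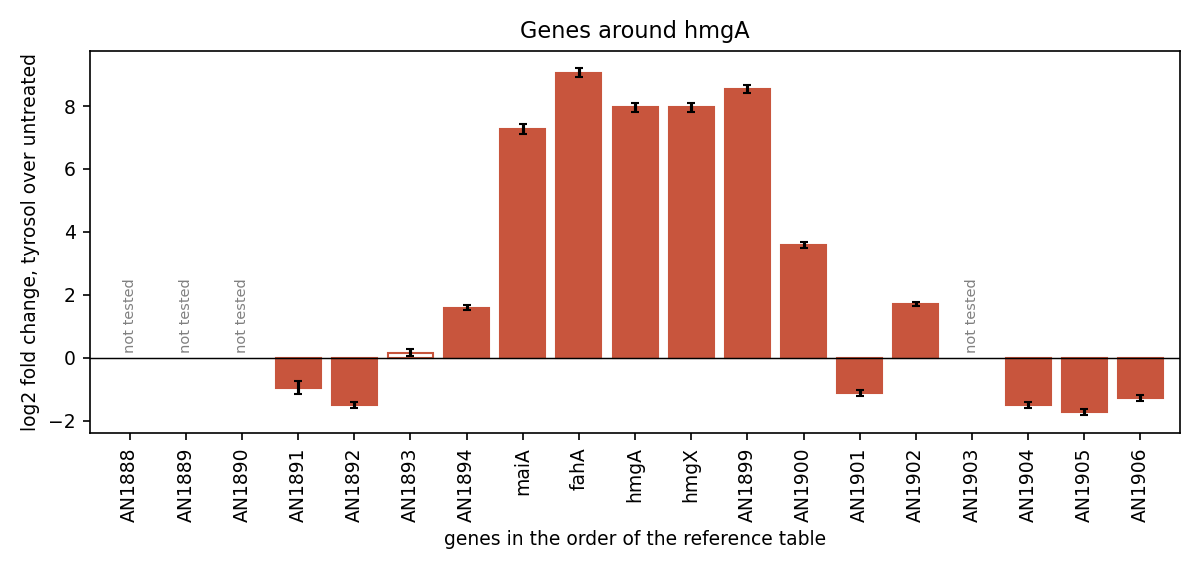
Log2 fold changes, tyrosol over untreated, of the genes around hmgA in the reference table's order, with bars of 1 SE; the white bar did not pass and genes marked as not tested had too few reads. The 5 genes from maiA to AN1899 stand at 7.28 to 9.06, and their other neighbours shown stay below 4.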

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

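The checks without the 50 features with most reads, with thinned libraries, with a length trend removed and against named features alone, and all tests of the added lists, were chosen after the data were seen; the other alternatives were planned. The count of 7432 changed genes ran from 6647 (at least 50 reads in 3 libraries, where 7794 features were tested) to 7762 (no filter on low counts), and from 7147 to 7526 with 1 library left out. The count of genes changed at least 2-fold, 4235, ran from 3539 (test against a 2-fold change) to 4589, and from 4249 to 4322 with 1 library left out. Leaving out a library lost 178 to 365 of the calls and reversed 0. The share of changed genes that rose was 48.7% with TMM and 41.1% with library size alone. With the replicate number as a block 7383 genes changed. Deviations of same-numbered libraries correlated at -0.08, -0.01 and -0.04, so no pairing by number was seen. With 3 libraries per group these values cannot exclude that same-numbered samples were handled together. Of the named genes 1 lost its call, pre3, a proteasome gene (log2 fold change 0.33). Its log2 fold change was 0.106 with library size alone (edgeR adjusted p = 0.299) and 0.111 with limma on RPKM (limma adjusted p = 0.266). The number of fixed lists moved, 2 of 8, was 1 with the 50-read filter (conidiation at adjusted p = 0.0567), 0 with an estimated correlation (0 at an unadjusted p under 0.05) and 7 with fry, which does not compare a list with other genes. It was 3, with plant polysaccharide and starch breakdown added, with library size alone, no filter on low counts, limma-voom and limma on RPKM. It was 2 to 3 with 1 library left out and 2 against named features alone, where plant polysaccharide and starch breakdown replaced conidiation. When the lists were extended with IDs assigned from memory, 3 of 23 moved, and 0 of them with an estimated correlation. Those 3 were tyrosine, homogentisate and phenylacetate breakdown (camera adjusted p = 0.00876), conidiation (0.0469) and antioxidant enzymes (0.0469). In the extended antioxidant list 11 of 13 genes rose and 2 fell. Of the added lists 8 of 20 moved, 7 to 10 with 1 library left out, 7 to 10 under other scalings, filters and tools, 7 with the replicate block (cytosolic ribosomal proteins at adjusted p = 0.0536), 7 against named features, 0 with an estimated correlation (3 at an unadjusted p under 0.05) and 18 with fry. Enrichment of fixed lists, 0 combinations, became 1 with the 2-fold threshold. The cause of these changes was not tested.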

Other observations

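The tests of composition, depth, length, gene order and runs were chosen after the fold changes had been seen, those of runs also after the result for genes 3 positions apart, and the splits of the libraries were planned. Long runs of neighbouring genes changed at least 2-fold in one direction. In the reference table's gene order 47 runs of 5 or more were found, 28 raised and 19 lowered, against at most 22 in 1000 shuffled orders; the longest held 10 genes, against 12 in the shuffled orders. That order held 8395 genes, against 10029 features paired with the reference table. Genes left out of the order may therefore lie between members of a run. The genes named here were chosen after their values were seen. The 7 genes from AN1894 to AN1900, which include maiA, fahA, hmgA and hmgX, had a median log2 fold change of 7.96. A raised run of 9 genes from AN9306 to AN9321 held mfs56 and had a median of 4.99, and another of 6 genes from AN2372 to AN2377 had a median of 6.44. A lowered run of 7 genes from AN8642 to AN8636 held catA and had a median of -3.71. A lowered run of 6 genes held the siderophore genes sidJ, mirD, sidD and sidH, with a median of -2.51.

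Whether such runs mark more than local gene order could be tested only in part. The rank correlation of log2 fold changes was 0.202 between adjacent genes and 0.0430 between genes 3 positions apart, where the highest of 1000 shuffled orders gave 0.0335, so reads shared by overlapping genes do not account for the correlation at that distance. Differences between untreated replicates correlated at 0.0471 to 0.0841 at that distance, the highest between replicates 1 and 3, and differences between tyrosol replicates at 0.00304 to 0.0219. The untreated values lie above the 0.0430 of tyrosol over untreated, so regional differences between replicates stay open for that correlation. Cut at the same ranks, the difference of untreated replicates 2 and 3 gave 48 runs of 5 or more, against 47 for tyrosol over untreated, and the other 5 pairs of replicates gave 20 to 31. Among every other gene there were 105 runs of 3 or more, against up to 109 in shuffled orders. Shared reads and regional differences between replicates both stay open for the number of runs, and no biological explanation of it was tested.

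The share of features that differ between the groups was weighed against 3 technical explanations. The 50 features with most reads held 13.2% of untreated and 16.4% of tyrosol reads, a change that shifts all other features by -0.0549 on the log2 scale, while 2057 features rose and 2178 fell at least 2-fold. With all libraries thinned to the smallest total the number of calls was 0.984 of that with all reads, and with a length trend removed from each library it was 1.01. Thinning and removing the length trend had little to take away: library totals ran from 9353438 to 11917409, and log2 fold change barely followed gene length (Spearman rho -0.0442). With so little of either, depth and length can hardly account for the number of calls. The 50 features carry only part of any composition difference, because library size alone in place of TMM shifted the median log2 fold change by -0.22. That scaling still called 7470 genes changed. Tyrosol exposure, which the design names, may be the source of the broad change.

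Other ways of splitting the 6 libraries into 3 and 3 number 10 with the real one, too few for a share under 0.05. Every other split mixes tyrosol and untreated libraries on each side. The difference between the groups then adds to the spread within a side and holds the calls down. Low counts in those splits follow from that mixing and give no measure of chance. The real split called 7432 genes by edgeR, and the highest of the others 0 (at most 14 at an unadjusted p under 0.05); 1 split, the real one, gave as many. For changes of at least 2-fold the values were 4235 and 0 (at most 5 at an unadjusted p under 0.05), again with 1 split as high. The real split moved 2 fixed lists and the highest of the others 1, and 1 split gave as many. Fisher's exact test enriched 0 combinations of list and direction in the real split (2 at an unadjusted p under 0.05) and 0 in the others (0 at an unadjusted p under 0.05), so 10 splits gave as many.

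A single library set the value of 1 abundant gene, chosen after its values were seen. AN5245 had 114431 reads in tyrosol replicate 2, which is 1.02% of that library, against 6583 and 8608 in tyrosol replicates 1 and 3 and 13226, 3897 and 4117 in the untreated libraries. Its log2 fold change of 2.84 ± 0.86 (edgeR adjusted p = 0.0081) rests on that library: without it the log2 fold change was 0.37 ± 0.37 (edgeR adjusted p = 0.374).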
